A study of Homo sapiens with 12 samples.

How the data were processed

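The samples were 12 total RNA samples of the human induced pluripotent stem cell line 201B6 taken at days 0, 2, 5, 7, 9 and 11 of differentiation toward cardiomyocytes in RPMI medium with B27 supplement, 2 samples per day, each on 1 array. Biotin-labelled cRNA was made from 250 ng of total RNA, per the labels, and the array type, Affymetrix Human Gene 1.0 ST, was read from the platform named in the header of the probe annotation. Each sample was placed in its day by its title, which also gives the replicate number 1 or 2. The sample descriptions also carry the number 2 for each replicate 1 and 6 for each replicate 2, and do not say what it marks.

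The deposited values are log2 signals per probe set, centred on each probe set's median over the 12 arrays. This was read from the values: the median of every one of the 28869 probe sets lies within 7.0e-07 of 0, and values run from -6.21 to 6.37. Centring by the authors removed the absolute level, so the values do not rank genes by how strongly they were expressed, and the planned filter on low values, which needs that rank, was not run. The log base was settled from the steps between values. All differences within a probe set (100.0%) were whole multiples of the inverse of 2 to the power 21, and in 33.98% of probe sets they were whole multiples of the inverse of 2 to the power 20, within 0.02 of a step. These are the steps of single-precision numbers from 4 to 8 and from 8 to 16, the range of log2 array signals, and log10 signals do not reach that far. Natural logs of a 16-bit scanner's signals end at 11.09, while 2 probe sets vary so widely that with every value at 4 or more they would pass it, the widest (8.02) reaching at least 12.02. The base was therefore taken as log2; the labels do not give it, and the folds rest on it. The 0.88% of values printed with 3 digits were left out of that check. The steps also leave a coarse mark of level: 9810 probe sets with at least 8 values to read kept the larger step throughout and were read as at 8 or above on every array. A value under 8 keeps that step by chance in 1 of 2 cases, and from the 1164 probe sets with exactly 1 value off it, at most about that many are expected to be misread. Background correction, normalization and probe summary are not given in the sources used here. The number of arrays limits the precision.

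Probe sets were named through the platform annotation of 2016: 19310 had 1 gene symbol, 1752 had several and 7807 were not listed. Symbols were updated by gene identifier through a gene table of assembly GRCh38.p14, used for names alone, which matched 19279 of the 19310. Probe sets with several genes or none named were left out of the gene tests, and the mean of a gene's probe sets was taken, giving 18377 genes, 685 of them with more than 1 probe set. The plan had been to keep the probe set with the highest mean, which has no meaning for centred values, so this was run as an alternative instead. POU5F1, NANOG and TNNT2 had been chosen to be named and are not analysed here, since no probe set is annotated to them alone. TDGF1 is given under its current symbol CRIPTO.

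Day means were fitted to all 12 arrays with limma 3.58.1 (R 4.3.3) with default empirical Bayes settings. An F-test compared the 6 days, and 7 differences between days were tested, each with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Comparisons that share a day share its 2 arrays and so its chance deviations. Before the data were examined, 32 gene lists were fixed, with 545 different members of which 493 were measured and 52 were not, and the list tests, comparisons, alternatives and rule for naming genes were fixed too. Lists were tested with camera at a preset correlation of 0.01, adjusted over 224 tests (32 lists in 7 comparisons), and 96 passed. With the correlation estimated from the data none passed (lowest adjusted p = 0.0958, 45 at an unadjusted p under 0.05). With fry, which asks whether the genes of a list move one way on balance without comparing them with other genes, 69 passed.

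Genes were named by a fixed rule. For each comparison it took the 5 largest rises and 5 largest falls among genes past the test whose higher day mean was at or above the median of all values (on centred values this depends on a gene's course and does not select by level), and up to 4 members of a list with the largest change, which could be named again elsewhere. VCAM1, SIRPA, NKX2-5, MYH6, TBXT and MESP1 were always to be named. Members given to complete a count of 5 or fewer, and GJA1, were named after their values were seen. XIST and genes of the Y chromosome were left out.

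The procedure was tested on simulated data with 200 changed genes among 18377 and the same design. The noise was drawn independently for each gene, with the same spread on all days. In the 7 simulated comparisons it recovered 71% to 82% of genes changed 2-fold and 91% to 99% of those changed 4-fold, with 4 to 13 false calls among 168 to 188. A shift of 0.5 (log2) in 1 list was found in 6 of 7 comparisons, and 1 other list passed. In the data, the estimated correlation within a list was 0.794 for the hepatic list and 0.482 for the sarcomere list. The simulation therefore does not show how often lists or genes pass wrongly under such correlation or with spreads that differ by day.

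The alternatives were quantile normalization, centring each array on its median, each probe set tested by itself, a variance trend with robust estimation, the replicate number as a second factor, only the 4 arrays of the 2 days compared, each array left out in turn, an estimated correlation and fry for the lists. Quantile normalization was run on the centred values, so it makes the spread of deviations from the gene medians equal between arrays. That spread differed by day, with a standard deviation over probe sets of 0.488 and 0.479 at day 0 and 0.267 and 0.295 at day 7. Making it equal therefore changes the size of differences between days, and does not test scaling of the signals themselves. After the data were seen, fits without both arrays of day 7, without both arrays of day 2, with the highest probe set and with only genes whose probe sets were all read as at 8 or above were added. Figures were drawn with matplotlib 3.10.9.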

Results

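RNA was profiled on 12 Affymetrix Human Gene 1.0 ST arrays while the human induced pluripotent stem cell line 201B6 differentiated toward cardiomyocytes. For each of 6 days (0, 2, 5, 7, 9 and 11) 2 arrays were run, called replicates 1 and 2 after their titles. The cells received Activin A from day 0 to day 1, BMP4 with bFGF from day 1 to day 5 and Dkk1, a secreted inhibitor of Wnt signalling, from day 5 to day 7. By the series' own design text, cardiomyocytes appeared after day 7 and made up about 50% of the cells at day 11. The number of arrays limits the precision of every value, and the labels do not say whether the 2 arrays of a day came from separate cultures. The p-values therefore measure the spread between these arrays, which may be technical. That spread is pooled, with 1 variance per gene for all 6 days. Across genes, the replicate difference had a standard deviation (SD) of 0.387 at day 2 and 0.382 at day 7. At days 0, 5, 9 and 11 it was 0.179, 0.191, 0.192 and 0.297. Comparisons with day 2 or day 7 may thus be judged against too small a spread. Each change below is the difference between 2 day means on the log2 scale ± its standard error (SE) from a limma fit of all 12 arrays, with n = 2 arrays per day. A gene is said to have risen or fallen where its Benjamini-Hochberg adjusted p was under 0.05.

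The 6 days were separated by large groups of genes. Among 18377 genes, 7749 (42.2%) differed between days in limma's F-test, and the day means of 3646 of them spanned at least 2-fold. Most of these 7749 genes were highest at one end of the course, with 2947 at day 0 and 1340 at day 11, while 1545 were highest at day 2, 702 at day 5, 486 at day 7 and 729 at day 9. SOX2, a core factor of pluripotent cells, stood 5.19 above its median on both day 0 arrays and at -0.43 and -0.20 at day 11. MIXL1, a homeobox gene of the primitive streak, reached 4.91 and 2.90 at day 2, and ISL1, a marker of cardiac progenitors, peaked at 1.74 and 1.67 at day 5. MYH6, the atrial myosin heavy chain, lay at -1.27 and -1.02 at day 5, at 4.59 and 1.02 at day 7 and at 5.13 and 5.08 at day 9. AFP, alpha-fetoprotein of the fetal liver and yolk sac, went from -2.43 and -2.32 at day 5 to 2.17 and 2.91 at day 7. The first principal component held 54.9% of the variance and ordered the days from 0 to 11 by the mean of their arrays, and the second held 18%. The correlation across genes between the 2 arrays was highest at day 0 (0.942, with 3 genes at least 2-fold apart). It was lowest at day 7 (0.261, 574 genes) and day 2 (0.627, 486 genes). On centred values it also depends on how far a day lies from the gene medians. Day 5 had a correlation of 0.796 (17 genes) with a replicate difference SD of 0.191, near the 0.179 of day 0.

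**Figure D1:**
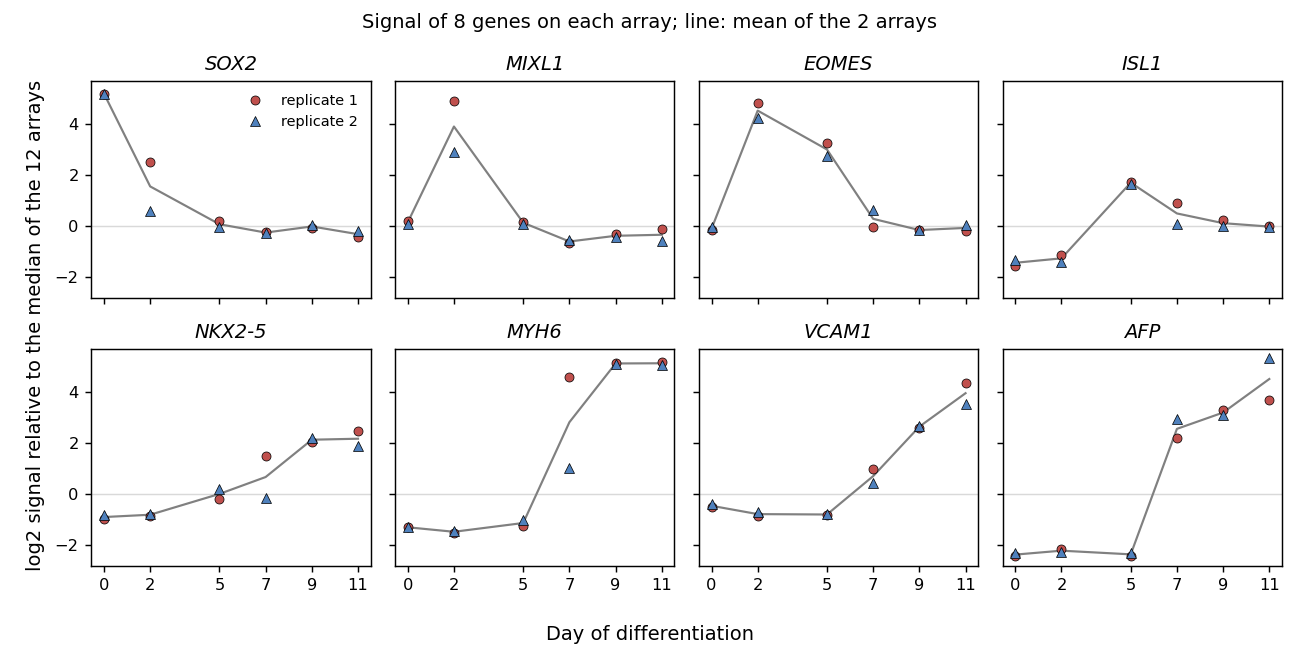
Signal of 8 genes on each of the 12 arrays, as log2 relative to the gene's median over the arrays (vertical axis), by day of differentiation (horizontal axis). Circles are replicate 1, triangles replicate 2 and the line joins day means; MYH6 stood at 4.59 and 1.02 on the 2 arrays of day 7, and VCAM1 at 4.34 and 3.53 on those of day 11.

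**Figure D2:**
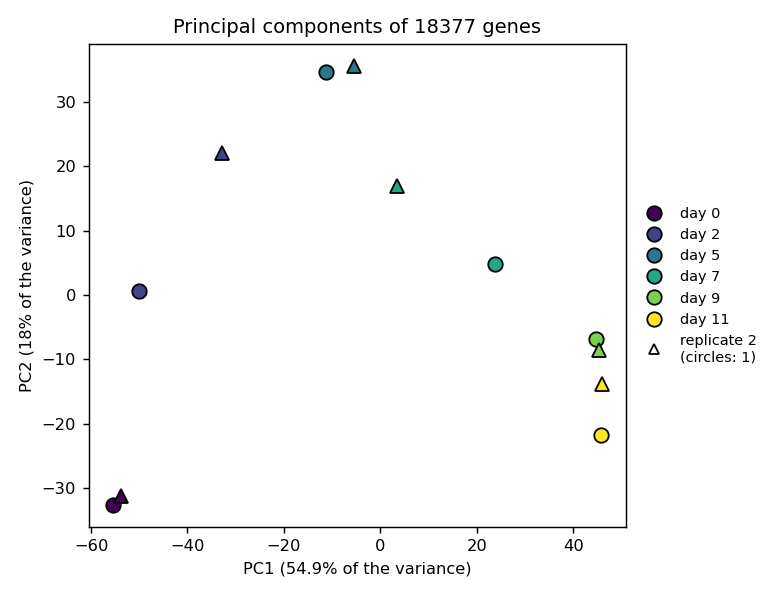
First and second principal components of the 12 arrays, in the units of the log2 values, with colour for the day, circles for replicate 1 and triangles for replicate 2. The arrays of day 2 (-50 and -32.9) and of day 7 (23.8 and 3.4) lie farthest apart along the first component, and those of day 9 (44.6 and 45.3) nearly coincide.

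The comparison of day 2 with day 0 asked what followed the Activin A pulse and the first day of BMP4 with bFGF. The largest rises were those of APLNR, the apelin receptor, by 5.39 ± 0.29 (41.8-fold, adjusted p = 1.02e-05), and of the transcription factors LHX1 by 4.75 ± 0.30 and EOMES by 4.63 ± 0.26 (adjusted p = 1.1e-05). DKK1, a secreted Wnt inhibitor, rose by 4.40 ± 0.56 and LGR5, an R-spondin receptor and Wnt target, by 4.21 ± 0.17. The largest falls were those of IDO1, a tryptophan-degrading enzyme (-3.74 ± 0.11), SOX2 (-3.64 ± 0.45), the secreted phosphoprotein SPP1 (-3.48 ± 0.50), the dNTP hydrolase SAMHD1 (-3.34 ± 0.26) and the deubiquitinase USP44 (-3.31 ± 0.31). TBXT (brachyury) rose by 1.90 ± 0.50 (adjusted p = 0.0455), with 2.92 on replicate 1 and 0.75 on replicate 2 of day 2, and MESP1 differed by 0.15 ± 0.15 (adjusted p = 0.713). In all, 1601 genes changed, of which 548 rose and 1053 fell, 251 and 403 of them at least 2-fold. After quantile normalization 603 genes passed, and 860 did with only the arrays of these 2 days. Without replicate 1 or replicate 2 of day 0 the number was 680 or 733.

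Of 18 measured genes of the primitive streak and early mesendoderm, 13 rose and 5 did not pass (14 rose adjusted over the list alone). The list's median was 1.65 (camera adjusted p = 4.07e-18; adjusted p = 0.125 with an estimated correlation). Its median per array stood at 2.15 and 1.18 above day 0 on replicates 1 and 2 of day 2. Among 12 definitive endoderm genes, 5 rose, 1 fell (CLDN6) and 6 did not pass (8 and 1 adjusted over the list alone; camera adjusted p = 9.45e-07; adjusted p = 0.216 with an estimated correlation). Here replicate 2 was the higher, at 2.07 against 0.67. CER1, an antagonist of Nodal and BMP, rose by 3.40 ± 0.19, PRDM1 by 3.19 ± 0.64 and SOX17 by 2.95 ± 0.32. Targets of BMP signalling rose in 9 of 16 cases (10 adjusted over the list alone), among them BMPER by 2.96 ± 0.28 and MSX2 by 2.88 ± 0.38 (camera adjusted p = 9.53e-09; adjusted p = 0.187 with an estimated correlation). Of 10 Nodal and Activin targets, 3 rose and 1 fell (3 and 2 adjusted over the list alone): EOMES and CER1 rose with GSC (1.68 ± 0.30), LEFTY1 fell by 1.79 ± 0.21. The 3 that rose are also on the streak list, and CER1 is on the endoderm list too. The Nodal and Activin list did not pass (camera adjusted p = 0.205). Its median was -0.04 and its mean 0.50. The median was 0.03 after quantile normalization and 0.29 without replicate 2 of day 2, where the list passed (adjusted p = 0.0274). Of 17 Wnt targets, 7 rose and 1 fell, WIF1 (8 and 1 adjusted over the list alone), with DKK1, LGR5 and DKK4 (3.72 ± 0.59) in front (camera adjusted p = 0.000219; adjusted p = 0.172 with an estimated correlation). The median of 0.20 was -0.01 after quantile normalization, 0.37 without replicate 2 of day 0 and 0.48 without replicate 1 of day 2, and the list passed in all 3. Of 16 FGF and ERK targets, 3 rose (5 rose and 1 fell adjusted over the list alone), the early response gene IER3 by 2.08 ± 0.18, IL17RD by 1.07 ± 0.17 and DUSP5 (camera adjusted p = 0.027; adjusted p = 0.216 with an estimated correlation). That list did not pass without replicate 1 of day 0 (adjusted p = 0.07) or replicate 2 of day 2 (adjusted p = 0.172).

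Of 17 pluripotency factors, 8 fell between day 0 and day 2 and 9 did not pass (8 adjusted over the list alone), with SOX2, USP44 and PRDM14 (-3.18 ± 0.38) in front (camera adjusted p = 3.05e-06; adjusted p = 0.358 with an estimated correlation). Of 16 epithelial junction and keratin genes, 3 fell (4 adjusted over the list alone), TJP3 (-1.64 ± 0.28), ST14 (-1.42 ± 0.24) and CLDN6 (camera adjusted p = 0.0033; adjusted p = 0.362 with an estimated correlation). CDH1, the epithelial cadherin, differed by -1.52 ± 0.44 (adjusted p = 0.0641), and whether it passed depended on which array of day 2 was left out. Of 13 genes of the mesenchymal transition, 8 rose (8 adjusted over the list alone), among them the transcription factor SNAI2 by 3.64 ± 0.42, the neural cadherin CDH2 by 2.08 ± 0.24 and SNAI1 by 1.75 ± 0.25 (camera adjusted p = 8.91e-08; adjusted p = 0.216 with an estimated correlation). Of 13 p53 targets, 7 fell (8 adjusted over the list alone), SESN1 (-1.24 ± 0.19) and RRM2B (-1.23 ± 0.16) in front (camera adjusted p = 2.6e-05; adjusted p = 0.216 with an estimated correlation). Of 22 genes of glycolysis and hypoxia, 3 fell (3 adjusted over the list alone), the glucose transporter SLC2A1 (-1.30 ± 0.25), PFKFB4 and PFKP (camera adjusted p = 0.00753; adjusted p = 0.517 with an estimated correlation). The glycolysis list did not pass without replicate 1 of day 0 (adjusted p = 0.0777) or replicate 1 of day 2 (adjusted p = 0.086). None of 15 genes of cholesterol synthesis passed, by limma over all genes or over the list alone, and the list did not either (median 0.09, camera adjusted p = 0.225). Of 17 genes of the integrated stress response, CHAC1 fell by 0.98 ± 0.25 and 16 did not pass (0 adjusted over the list alone; camera adjusted p = 0.245). Of the 36 genes named for this comparison that passed, 25 did so whichever array of days 0 and 2 was left out. The calls of CHAC1, CLDN6, DUSP5, GSC, PFKFB4, PFKP, PRDM1, SLC2A1, ST14, TBXT and TJP3 ended without 1 of them (adjusted p from 0.0509 to 0.294).

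Day 5 against day 2 covered the rest of the BMP4 and bFGF treatment. Of 20 genes of lateral and cardiogenic mesoderm, 13 rose and 7 did not pass (14 rose and 1 fell adjusted over the list alone). Their median was 1.80 (camera adjusted p = 2.5e-13; adjusted p = 0.165 with an estimated correlation). The homeobox genes MEIS1 and MEIS2 rose by 3.32 ± 0.51 and 3.07 ± 0.27, TMEM88, a membrane protein that dampens Wnt signalling, by 3.15 ± 0.41 and ISL1 by 2.96 ± 0.23. Outside that list, the largest rises were those of DLK1, a membrane protein related to Notch ligands (3.54 ± 0.48), the diacylglycerol kinase DGKK (3.44 ± 0.49) and the serine protease HTRA1 (3.37 ± 0.30). The largest falls were those of CER1 (-5.22 ± 0.19), the surface glycoprotein CD177 (-3.80 ± 0.19), MIXL1 (-3.77 ± 0.48), the Wnt inhibitor DKK4 (-3.58 ± 0.59) and FGF17 (-3.41 ± 0.16). Of the 18 streak genes, 9 fell and 9 did not pass (13 adjusted over the list alone; camera adjusted p = 1.53e-08; adjusted p = 0.172 with an estimated correlation). TBXT differed by -1.64 ± 0.50 (adjusted p = 0.0718). That difference was larger without replicate 2 of day 2, where TBXT stood lower, and smaller without replicate 1. Of the 10 Nodal and Activin targets, 5 fell, among them LEFTY2 (-1.79 ± 0.33) (7 adjusted over the list alone; camera adjusted p = 0.000101; adjusted p = 0.165 with an estimated correlation).

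Of 13 mesenchymal genes, 5 rose between day 2 and day 5 (6 rose and 1 fell adjusted over the list alone), including the cadherin CDH11 by 2.48 ± 0.22 and PRRX1 by 2.20 ± 0.22 (camera adjusted p = 9.79e-05; adjusted p = 0.351 with an estimated correlation). Of 16 BMP targets, 6 rose (9 adjusted over the list alone), among them BMP4 itself by 2.31 ± 0.21 and GATA3 by 2.09 ± 0.33 (camera adjusted p = 5.88e-08; adjusted p = 0.205 with an estimated correlation). Of 14 trophoblast and amnion genes, 3 rose (3 adjusted over the list alone; camera adjusted p = 0.000535; adjusted p = 0.165 with an estimated correlation): these were ISL1, GATA3 and GATA2 (0.83 ± 0.15), transcription factors that cardiac or other mesoderm also uses. Of 16 epithelial genes, 3 rose and 1 fell (3 and 3 adjusted over the list alone), the keratins KRT19 (1.66 ± 0.41), KRT18 (1.32 ± 0.25) and KRT8 (1.06 ± 0.22) up and CLDN6 down. As a list they did not pass (camera adjusted p = 0.477). One of 15 paraxial mesoderm and skeletal muscle genes, FOXC2, rose, by 0.79 ± 0.18 (1 adjusted over the list alone; camera adjusted p = 0.174). Of 24 proliferation genes, 7 fell (12 adjusted over the list alone; camera adjusted p = 1.1e-05; adjusted p = 0.362 with an estimated correlation). In all, 1550 genes changed, 558 up and 992 down, 250 and 193 of them at least 2-fold. After quantile normalization the split was 821 up and 797 down. With only genes read as at 8 or above on every array it was 254 up and 879 down. The median change was -0.15 in these genes and -0.02 in all genes. With only the arrays of these 2 days 224 genes passed (148 up, 76 down). Without replicate 1 or 2 of day 2 the number was 635 or 3600, and without replicate 1 or 2 of day 5 it was 297 or 191 (117 up, 74 down in the latter). Leaving out 1 array ended the calls of CLDN6, DGKK, DKK4, FOXC2, GATA2, GATA3, KRT18, KRT19, KRT8, LEFTY2 and MEIS1 (adjusted p from 0.0519 to 0.236). The other 12 named genes that passed did so whichever array was left out.

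Day 7 against day 5 set cells after the Dkk1 treatment against cells before it. The largest rises were those of TTR (transthyretin) by 5.37 ± 0.52 (41.3-fold, adjusted p = 0.000883), AFP by 4.92 ± 0.42, the peptidase DPP4 by 4.43 ± 0.72, the fibrinogen chain FGB by 4.32 ± 0.68 and MTTP, which loads lipid onto lipoproteins, by 4.27 ± 0.55. Of 17 genes on the hepatic list, 7 rose and 10 did not pass (9 adjusted over the list alone; camera adjusted p = 1.19e-10; adjusted p = 0.358 with an estimated correlation). Its median stood 1.87 above day 0 on replicate 1 and 2.35 on replicate 2. The genes that fell most were RIPPLY1, a transcriptional repressor of somite formation (-4.23 ± 0.44), CYP26A1, which degrades retinoic acid (-3.53 ± 0.31), SAMD3 (-3.18 ± 0.35), the kinase ZAP70 (-3.02 ± 0.35) and the transcription factor EBF2 (-3.02 ± 0.41). EOMES fell by 2.72 ± 0.26. Of 17 Wnt targets, LGR5 fell by 1.33 ± 0.17 and TNFRSF19 rose by 1.06 ± 0.21 (1 and 1 adjusted over the list alone). As a list the Wnt targets did not pass (median -0.11, camera adjusted p = 0.217). That median was -0.02 without replicate 2 of day 7, -0.18 after quantile normalization and -0.28 with only genes at 8 or above. The list did not pass in any of these fits. In all, 603 genes changed, of which 320 rose and 283 fell, 166 and 152 of them at least 2-fold. With only genes at 8 or above, 159 rose and 100 fell, and their median change was 0.06.

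Between day 5 and day 7, 4 of 28 sarcomere genes rose and 24 did not pass (14 adjusted over the list alone), MYH6 by 3.95 ± 0.82 (adjusted p = 0.0325), ACTC1, cardiac alpha-actin, by 2.72 ± 0.54, MYL4 by 2.63 ± 0.45 and NEXN (median 1.04, camera adjusted p = 3.27e-07; adjusted p = 0.438 with an estimated correlation and 0.114 by fry). The median was 0.34 without replicate 1 of day 7 and 1.79 without replicate 2. The median of that list stood 2.58 above day 0 on replicate 1 of day 7 and 0.61 on replicate 2. Of 24 cardiac transcription factors, 3 rose and 2 fell (6 and 2 adjusted over the list alone), SMYD1 (3.57 ± 0.73), MEF2C (3.34 ± 0.59) and GATA4 up and IRX3 and ISL1 (-1.21 ± 0.23) down. This list did not pass (camera adjusted p = 0.0549). It passed without replicate 2 of day 7 (adjusted p = 2.96e-08) or replicate 2 of day 5 (adjusted p = 0.013). NKX2-5 differed by 0.66 ± 0.42 (adjusted p = 0.502), by -0.17 without replicate 1 of day 7 and by 1.496 without replicate 2, where it passed (adjusted p = 0.00672). ACTA2, smooth muscle actin, rose by 3.78 ± 0.44. VCAM1, a cell adhesion molecule, rose by 1.503 ± 0.25 (adjusted p = 0.011). The number of changed genes was 1898 after quantile normalization (892 up, 1006 down), 154 with only the arrays of these 2 days (61 up, 93 down), 968 with the day 2 arrays left out of the fit, and 104 or 162 without replicate 1 or 2 of day 5. It was 824 without replicate 1 of day 7 (542 up, 282 down) and 769 without replicate 2 (524 up, 245 down). Leaving out 1 array of day 5 or day 7 ended the calls of 15 of the 24 named genes that passed, among them MYH6, ACTC1, MEF2C, SMYD1, VCAM1, FGB, DPP4, MTTP and EBF2 (adjusted p from 0.0521 to 0.264 over the 15). TTR, AFP, RIPPLY1, CYP26A1, SAMD3, ZAP70, EOMES, LGR5 and ACTA2 passed without any 1 array.

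The step from day 7 to day 9 was the first after the day at which, by the series' design text, no cardiomyocytes had yet appeared. The median of the sarcomere list already stood 2.58 above day 0 on replicate 1 of day 7, and 0.61 on replicate 2, against 3.23 and 3.28 at day 9. Of 28 sarcomere genes, 10 rose and 18 did not pass (17 adjusted over the list alone), led by MYL3, a cardiac myosin light chain, by 3.45 ± 0.53 and LDB3, a Z-disc protein, by 2.73 ± 0.61 (median 1.26, camera adjusted p = 2.66e-13; adjusted p = 0.27 with an estimated correlation). The median was 1.94 without replicate 1 of day 7 and 0.38 without replicate 2. Of 23 genes of calcium handling and ion channels, 10 rose and 1 fell (15 and 1 adjusted over the list alone), among them KCNIP2, a subunit of potassium channels, by 3.32 ± 0.36 and RYR2, the calcium release channel, by 2.53 ± 0.46 (camera adjusted p = 9.27e-10; adjusted p = 0.216 with an estimated correlation). GJA1, the gap junction protein connexin 43, was the member that fell (-2.08 ± 0.33). Of 16 epithelial genes, RAB25 (-1.26 ± 0.32) and ESRP2 (-1.10 ± 0.26) fell (5 adjusted over the list alone; median -0.51, camera adjusted p = 9.79e-05; adjusted p = 0.242 with an estimated correlation). Other lists that passed, none of them with an estimated correlation, were those of cardiac hormones and energy metabolism (median 0.66), cardiac transcription factors (0.77), glycolysis (0.44), smooth muscle (0.32) and extracellular matrix (0.23), and, downward, of pluripotency factors (-0.57), definitive endoderm (-0.65) and cholesterol synthesis (-0.40). Without replicate 2 of day 7 the lists of cardiac transcription factors (0.09, adjusted p = 0.0941), glycolysis (0.13, adjusted p = 0.148), smooth muscle (-0.09, adjusted p = 0.828) and matrix (0.01, adjusted p = 0.654) did not pass. The smooth muscle and matrix lists did not pass after quantile normalization (adjusted p = 0.158 and 0.307) or without replicate 1 of day 9 (0.13 and 0.132) either. Without replicate 1 of day 7 the medians of the matrix and definitive endoderm lists were 0.51 and -1.07, and without its replicate 2 that of the latter was -0.35. The basement membrane chain LAMA4 rose by 3.44 ± 0.14, the protease inhibitor A2M by 3.32 ± 0.28 and CORIN, the protease that activates atrial natriuretic peptide, by 3.23 ± 0.24. VCAM1 rose by 1.94 ± 0.25 (adjusted p = 0.00435). The genes that fell most were CST1, a cystatin (-4.26 ± 0.99), AMBN, known from tooth enamel (-2.78 ± 0.30), the cytochrome P450 gene CYP4X1 (-2.63 ± 0.44), DENND2C (-2.41 ± 0.53) and the glycosyltransferase UGT3A2 (-2.27 ± 0.22). Of 24 proliferation genes, 22 fell and 2 did not pass (24 adjusted over the list alone), including CDK1 (-1.06 ± 0.12) and MCM4 (-1.11 ± 0.14), with a median of -0.84 (camera adjusted p = 6.44e-23; adjusted p = 0.165 with an estimated correlation). In all, 997 genes changed, 388 up and 609 down, 177 and 107 at least 2-fold. With only genes at 8 or above, 179 rose and 629 fell. The median change was -0.11 in these genes and -0.003 in all genes. Over all genes the number was 7 with only the arrays of these 2 days (6 up, 1 down) and 1634 with the day 2 arrays left out of the fit. It was 1916 or 347 without replicate 1 or 2 of day 7 and 104 or 117 (63 up, 54 down) without replicate 1 or 2 of day 9. The calls of CST1, CYP4X1, DENND2C, ESRP2, GJA1, LDB3, MYL3, RAB25 and RYR2 ended without 1 of these arrays (adjusted p from 0.0544 to 0.261), and those of the other 9 named genes did not.

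Between day 9 and day 11 few genes passed. Of 27 that changed, 16 rose and 11 fell, 11 and 10 of them at least 2-fold. The largest rises were those of the clotting genes FGG (2.63 ± 0.39, adjusted p = 0.0438) and SERPIND1 (2.20 ± 0.31), the matrix protein POSTN (1.92 ± 0.27), the muscle gene MLIP (1.88 ± 0.25) and the protocadherin PCDHB14 (1.51 ± 0.21). The falls were led by NPY, neuropeptide Y (-2.52 ± 0.29), OIT3 (-1.80 ± 0.25), the matrix protein THBS4 (-1.48 ± 0.17), MAOA, which oxidizes monoamines (-1.15 ± 0.11), and DYNLT5 (-1.02 ± 0.14). Of 15 genes of cholesterol synthesis, 3 rose over all genes (11 adjusted over the list alone), HMGCS1 by 1.09 ± 0.14, DHCR7 by 0.84 ± 0.13 and NSDHL by 0.75 ± 0.11 (median 0.71, camera adjusted p = 1.42e-17; adjusted p = 0.0958 with an estimated correlation). On the hepatic list 1 of 17 rose, FGG (1 adjusted over the list alone; camera adjusted p = 2.33e-05; adjusted p = 0.517 with an estimated correlation). Its median stood 2.52 above day 0 on replicate 1 of day 11 and 4.69 on replicate 2. Without that replicate 2 the list's change was -0.09 and did not pass (adjusted p = 0.903). VCAM1 differed by 1.31 ± 0.25 (adjusted p = 0.105). That difference was larger without replicate 2 of day 11, where VCAM1 stood lower, and smaller without replicate 1. At an unadjusted p under 0.05, 1421 of 18377 genes differed in limma, where a share of 0.05 would be expected with no change at all. The count was 14 after quantile normalization (6 up, 8 down), 12 with a trend in the variance, 1 or 0 without replicate 1 or 2 of day 9 and 45 without replicate 2 of day 11 (38 up, 7 down). Each of the 13 named genes that passed lost its call without at least 1 array (adjusted p from 0.0573 to 0.6).

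**Figure D3:**
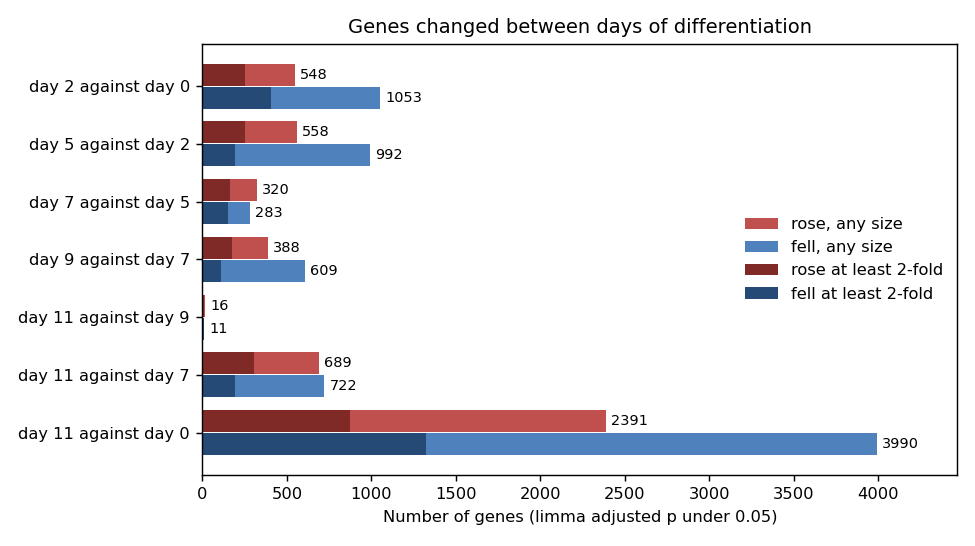
Number of genes that rose or fell in each comparison of 2 days (horizontal axis, from 0), at a limma adjusted p under 0.05, with the part that changed at least 2-fold in the darker shade. The counts run from 16 up and 11 down for day 11 against day 9 to 2391 up and 3990 down for day 11 against day 0.

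By the series' design text, the interval from day 7 to day 11 holds the time in which cardiomyocytes appeared. The comparison asked which genes, surface molecules among them, changed over it. VCAM1 rose by 3.25 ± 0.25 (adjusted p = 0.000276), with 0.97 and 0.41 on the arrays of day 7 and 4.34 and 3.53 on those of day 11. SIRPA, a surface receptor also used to sort human cardiomyocytes, rose by 1.07 ± 0.27 (adjusted p = 0.041). Of 19 surface antigens used for sorting, 2 rose (VCAM1 and SIRPA), 3 fell (EPCAM at -1.82 ± 0.43, PODXL and PDGFRA), and 14 did not pass (4 rose and 7 fell adjusted over the list alone). As a group these antigens did not pass (camera adjusted p = 0.919), with a median of 0.18 and a mean of -0.09. That median was -0.08 without replicate 1 of day 7, and -0.002 or -0.16 without replicate 1 or 2 of day 11. The receptor gene KIT differed by -2.02 ± 0.55 (adjusted p = 0.0534), and whether it passed depended on which array of day 7 was left out. The largest rises of all were those of the nuclear receptor RXRG (4.18 ± 0.21), A2M (4.02 ± 0.28), the muscle gene SMPX (3.88 ± 0.92), MYL3 (3.81 ± 0.53) and LAMA4 (3.75 ± 0.14). CST1 (-4.31 ± 0.99), the amino acid transporter SLC7A3 (-3.18 ± 0.17), AMBN (-2.82 ± 0.30), NPY (-2.80 ± 0.29) and DENND2C (-2.71 ± 0.53) fell most. In all, 1411 genes changed, 689 up and 722 down, 304 and 191 at least 2-fold. With only genes at 8 or above, 311 rose and 576 fell, and their median change was -0.07.

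Over the same interval 13 of 28 sarcomere genes rose and 15 did not pass (23 adjusted over the list alone), MYOM1 of the M band by 3.27 ± 0.48 and LDB3 by 3.15 ± 0.61 among them (median 1.60, camera adjusted p = 3.61e-14; adjusted p = 0.245 with an estimated correlation). That median was 1.02 after quantile normalization, 2.37 without replicate 1 of day 7 and 0.62 without replicate 2, and the list passed each time. Of 23 calcium handling and channel genes, 12 rose and 1 fell (16 and 1 adjusted over the list alone), TRDN by 2.99 ± 0.29, PLN (phospholamban) by 2.96 ± 0.59 and CACNB2 by 2.75 ± 0.31 (camera adjusted p = 1.15e-09; adjusted p = 0.216 with an estimated correlation). GJA1 fell by 2.38 ± 0.33. Of 20 genes of cardiac hormones and energy metabolism, 8 rose (12 adjusted over the list alone), CKM (muscle creatine kinase) by 3.11 ± 0.25 and HSPB7 by 2.92 ± 0.31 (camera adjusted p = 1.44e-08; adjusted p = 0.172 with an estimated correlation). MYH6 differed by 2.31 ± 0.82 (adjusted p = 0.131) and NKX2-5 by 1.5 ± 0.42 (adjusted p = 0.0622). Without replicate 1 of day 7 these differences were 4.09 and 2.34. Without its replicate 2, where both genes stood lower, they were smaller than with both arrays. Of 17 hepatic and visceral endoderm genes, 5 rose (6 adjusted over the list alone), AHSG by 3.47 ± 0.52, TF by 2.76 ± 0.55, SERPINA1 by 2.52 ± 0.60, FGG and AFP (median 0.60, camera adjusted p = 0.0054; adjusted p = 0.656 with an estimated correlation). The hepatic list did not pass after quantile normalization (adjusted p = 0.288), without replicate 1 of day 7 (adjusted p = 0.315) or without replicate 2 of day 11, where its median was -0.055 (adjusted p = 0.551); without replicate 2 of day 7 or replicate 1 of day 11 the median was 1.24 or 1.61. Of 16 epithelial genes, RAB25 (-1.89 ± 0.32), EPCAM and ESRP2 fell (7 adjusted over the list alone; median -0.72, camera adjusted p = 1.99e-06; adjusted p = 0.206 with an estimated correlation). On the smooth muscle list 2 of 15 genes rose (4 adjusted over the list alone; camera adjusted p = 0.0291; adjusted p = 0.527 with an estimated correlation), namely PLN, which is on both lists, and MYH11. That list did not pass after quantile normalization (adjusted p = 0.168), without replicate 2 of day 7 (adjusted p = 0.523) or without replicate 2 of day 11 (adjusted p = 0.131). None of 21 endothelial genes passed in limma, over all genes or over the list alone (camera adjusted p = 0.0659). This list passed downward without replicate 1 of day 7 (adjusted p = 6.73e-05) or replicate 2 of day 11 (adjusted p = 0.00192) and after quantile normalization (adjusted p = 0.0384), and its median was 0.01 without replicate 1 of day 11. Of 12 epicardial genes, TBX18 rose by 1.66 ± 0.13 (2 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.184), and the median of 0.28 was -0.01 without replicate 2 of day 11. Of 24 proliferation genes, 17 fell (23 adjusted over the list alone; camera adjusted p = 7.21e-22; adjusted p = 0.165 with an estimated correlation). The 1411 changed genes became 8 with only the arrays of these 2 days (6 up, 2 down), 780 without replicate 2 of day 7, 503 without replicate 1 of day 11 (260 up, 243 down) and 1097 without its replicate 2 (689 up, 408 down). Without 1 array of days 7 or 11 the calls of AFP, CST1, DENND2C, EPCAM, ESRP2, LDB3, MYH11, PDGFRA, PLN, PODXL, RAB25, SERPINA1, SIRPA, SMPX and TF ended (adjusted p from 0.0534 to 0.209). Another 17 named genes, VCAM1 among them, passed in each such fit. With only the 4 arrays of these days VCAM1 had an adjusted p of 0.0763.

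**Figure D4:**
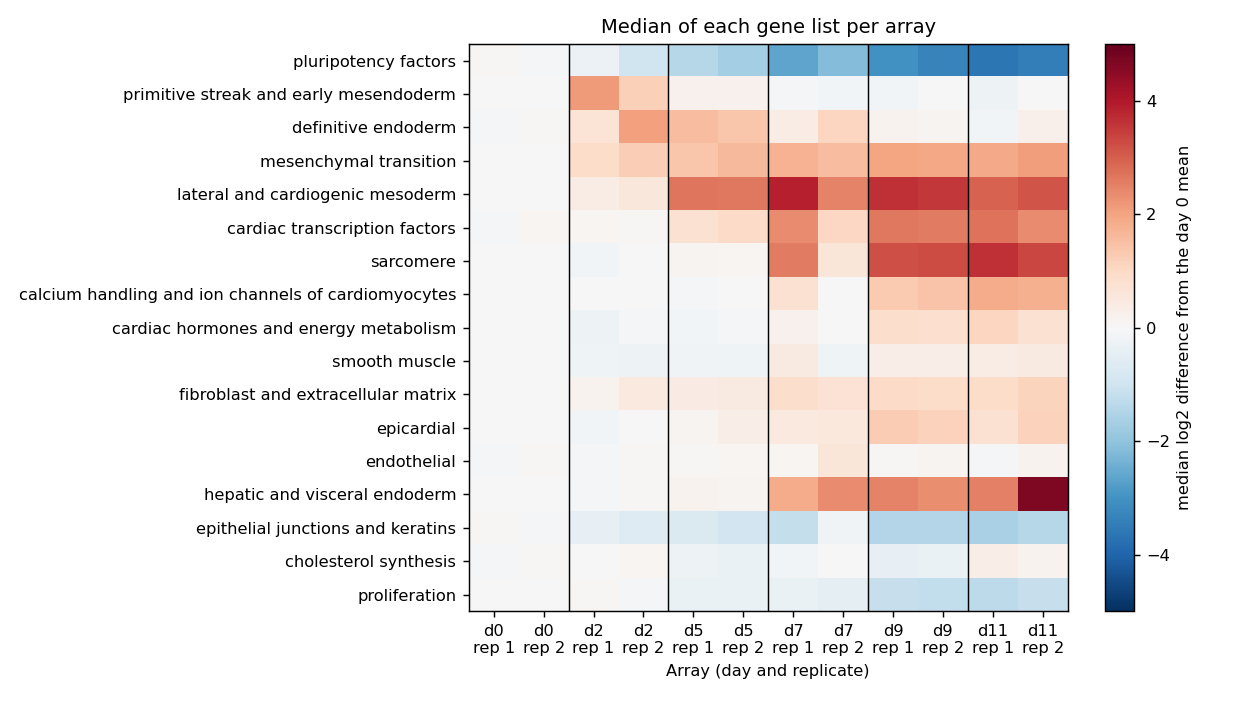
Median of 17 gene lists on each of the 12 arrays (columns, by day and replicate), as the log2 difference from the mean of the day 0 arrays, in blue below and red above 0. The sarcomere list stood at 2.58 and 0.61 on the arrays of day 7 and at 3.66 and 3.35 on those of day 11, and the hepatic list at 2.52 and 4.69 on those of day 11.

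Day 11 against day 0 compared the end of the course with undifferentiated cells. TECRL, an endoplasmic reticulum protein of heart muscle, rose by 7.72 ± 0.38 (211-fold, adjusted p = 2.69e-06), AFP by 6.88 ± 0.42, SMPX by 6.75 ± 0.92, MYH6 by 6.42 ± 0.82 and LIX1 by 6.39 ± 0.69. VCAM1 rose by 4.41 ± 0.25, NKX2-5, a core factor of heart development, by 3.07 ± 0.42 and SIRPA by 1.87 ± 0.27. SOX2 (-5.51 ± 0.45), the microRNA precursors MIR302B (-5.15 ± 0.85) and MIR302A (-4.92 ± 0.98), the p53 target PMAIP1 (-5.11 ± 0.38) and USP44 (-4.996 ± 0.31) fell most. All 17 pluripotency factors fell (17 adjusted over the list alone; median -3.63, camera adjusted p = 2.82e-12; adjusted p = 0.21 with an estimated correlation). Of 28 sarcomere genes, 24 rose and 1 fell, the actin ACTA1 (-1.35 ± 0.31) (24 and 1 adjusted over the list alone; camera adjusted p = 2.39e-13; adjusted p = 0.27 with an estimated correlation). Among 24 cardiac transcription factors 20 rose (20 adjusted over the list alone), HAND1 by 5.48 ± 0.19 among them (camera adjusted p = 5.07e-14; adjusted p = 0.187 with an estimated correlation). In all, 6381 genes changed, 2391 up and 3990 down, 874 and 1324 of them at least 2-fold. The number was 4146 after quantile normalization and 3948 or 4176 without replicate 1 or 2 of day 0. With only genes at 8 or above, 1024 rose and 2322 fell. The median change was -0.14 in these genes and -0.01 in all genes.

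Genes of other lineages had also changed by day 11. Of 17 hepatic and visceral endoderm genes, 16 rose and 1 did not pass (17 adjusted over the list alone), FGB by 5.26 ± 0.68 and TTR by 4.89 ± 0.52 among them (median 3.68, camera adjusted p = 4.57e-10; adjusted p = 0.362 with an estimated correlation). Of 24 fibroblast and extracellular matrix genes, 16 rose and 1 fell (17 and 1 adjusted over the list alone), the proteoglycan LUM by 6.05 ± 0.29 and collagen COL3A1 by 2.95 ± 0.20, while THY1 fell by 3.20 ± 0.27 (camera adjusted p = 1.91e-08; adjusted p = 0.187 with an estimated correlation). Of 11 anterior HOX genes, 4 rose (4 adjusted over the list alone), HOXB2 by 2.86 ± 0.28, HOXB3 by 1.66 ± 0.25, HOXB6 and HOXB4 (camera adjusted p = 0.0145; adjusted p = 0.285 with an estimated correlation). The HOX list did not pass without replicate 2 of day 11 (adjusted p = 0.0546). Of 24 proliferation genes, 23 fell (23 adjusted over the list alone), BUB1B of the spindle checkpoint at -1.77 ± 0.12 among them (median -1.21, camera adjusted p = 5.06e-13; adjusted p = 0.205 with an estimated correlation). Of 15 neural ectoderm genes, 2 rose and 3 fell (2 and 3 adjusted over the list alone), the adhesion molecule NCAM1 (3.04 ± 0.37) and LHX2 up and ELAVL3 (-1.35 ± 0.12), DCX and OTX2 down (camera adjusted p = 0.901). Of 12 neural crest genes, 1 rose (SNAI2, by 3.61 ± 0.42) and 3 fell, EDNRB, ERBB3 and FOXD3 (1 and 3 adjusted over the list alone; camera adjusted p = 0.918). Of 15 haematopoietic genes, ITGA2B fell by 0.49 ± 0.14 (0 adjusted over the list alone; camera adjusted p = 0.507). The medians of these 3 lists (-0.08, 0.01 and 0.10) were within 0.1 of 0, and their sign changed without 1 or the other array of day 11, to 0.04, -0.11 and -0.01. Of 11 housekeeping genes, 1 rose (SDHA, by 0.44 ± 0.11) and 4 fell, TFRC (-1.31 ± 0.16), HPRT1 (-1.26 ± 0.23), GUSB and TBP (2 and 6 adjusted over the list alone; camera adjusted p = 0.115). Without 1 array of day 0 or day 11 the calls of ACTA1, DCX, ERBB3, HOXB4, HOXB6, ITGA2B, SDHA and TBP ended (adjusted p from 0.0522 to 0.168), and those of the other 32 genes named for this comparison did not.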

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

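The tests in this part that were chosen after their result was seen are those of a delay and of other cells at day 7, of progress along the course at day 2, and both tests on cholesterol synthesis. The tests of array noise were first run on 339 olfactory receptor genes (ratio 0.936 at day 7 and 1.005 at day 2), none of which was read, from the steps between values, as at 8 or above on every array and which carry no weight here, and were then set on ribosomal protein genes before the values of these were seen (47 of 61 read as at 8 or above).

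Probe sets outside the gene tests also carried a signal. Among the 7807 probe sets not listed in the annotation, 1003 (12.8%) changed between day 0 and day 11 in limma, 686 up and 317 down, 151 and 114 of them at least 2-fold. Among the 1752 annotated to several genes, 832 (47.5%) did, 517 up and 315 down. Of the genes with a probe set of their own 34.7% changed. Each of these sets was fitted and adjusted by itself, the first 2 per probe set and the last per gene, so the shares are not directly comparable.

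The 2 arrays of day 7 differed in heart muscle genes: 26 of 28 sarcomere genes were higher on replicate 1, by a median of 1.47. Noise across an array is argued against by 61 ribosomal protein genes, whose replicate difference had a standard deviation (SD) at day 7 of 1.001 times the largest of days 0, 5 and 9. A common delay of replicate 2 is argued against by the hepatic genes, which rose over the same days: 16 of 17 were higher on replicate 2, with a median of replicate 1 minus replicate 2 of -0.602. A delay of part of the genes, heart muscle genes among them, stays open, since across genes replicate 1 minus replicate 2 correlated at 0.399 with day 9 minus day 5, and replicate 2 lay closer to day 5 in its medians, relative to day 0, of pluripotency factors (-2.17 against -2.63 on replicate 1), Nodal and Activin targets (-2.28 against -2.75) and the precursors MIR302A and MIR302B (-0.03 against -3.81). A larger share of other cells in replicate 2 stays open too: of 5 lists of other cell types, 16 of 17 hepatic, 19 of 21 endothelial, 14 of 16 epithelial and 8 of 12 epicardial genes were higher on replicate 2 (medians of replicate 1 minus replicate 2 of -0.602, -0.586, -0.375 and -0.091), while the lowest median of replicate 2 minus replicate 1 was -0.173, for extracellular matrix genes, with quartiles on both sides of 0. Outside these 5 lists, 12 of 13 mesenchymal transition and 12 of 15 smooth muscle genes were higher on replicate 1 (medians of replicate 1 minus replicate 2 of 0.317 and 0.51). The labels tell the replicates apart only by number, 2 and 6 in the descriptions, without saying what it marks, and no other biological explanation was tested.

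At day 2 replicate 1 was higher in streak genes (2.15 against 1.18 above day 0) and replicate 2 in endoderm genes (2.07 against 0.67). Noise across an array is argued against by the ribosomal protein genes, with a ratio of 1.283 to the largest SD of days 0, 5 and 9. A candidate explanation is that replicate 2 was further along the course: of 1326 genes at least 2-fold apart between days 0 and 5, replicate 2 lay further toward day 5 in 77.5%. A sampling time and a culture that ran faster were not separated here, and no other biological explanation was tested.

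Cholesterol synthesis genes were higher at day 11 than at day 9 by a median of 0.71. Scaling between arrays was tested by quantile normalization, after which a median of 0.643 remained. That normalization was run on centred values, so it cannot decide whether the signals were scaled differently. The median change of all genes between these days was 0.01. It was 0.05 among genes at 8 or above, which include 14 of the 15 cholesterol genes. The deposited values thus hold no common shift of the size of 0.71. Every array's median lay near 0 (from -0.029 to 0.022), so a shift removed in processing would not be seen. Liver cells make cholesterol, but the list was lower on the day 11 replicate with the higher hepatic list, by a median of -0.148 for replicate 2 minus replicate 1, and on replicate 1 the hepatic list stood at 2.52, against 2.47 and 2.31 at day 9. The list's median per array, relative to the mean of day 0, had also gone up and down earlier, from 0.04 and 0.12 at day 2 to -0.27 and -0.33 at day 5, -0.13 and -0.03 at day 7 and -0.40 and -0.35 at day 9, before 0.34 and 0.19 at day 11. Against day 7 the median at day 11 was 0.28, with 2 of 15 genes risen (camera adjusted p = 0.00196, and 0.216 with an estimated correlation). That median was 0.18 without replicate 2 of day 7, and the list did not pass without replicate 1 of day 11. The time since the last change of medium is not in the labels, and no biological explanation other than more hepatic cells was tested.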

How the results depend on the processing

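The fits without both arrays of day 7, without both arrays of day 2, with the highest probe set per gene and with only genes read as at 8 or above on every array were chosen after the data were seen. The planned filter on low values was not run, because it needs levels, which centring removed, and other pseudocounts did not apply to log2 values. Signal over background was not measured. The steps between values give only a coarse mark of level, by which 7632 genes (41.5%) were at 8 or above on every array; in the test of all genes 52.5% of these differed between days, against 34.8% of the others. Where an array was left out, the lone array of its day is assumed to vary like the others. The cause of the shifts below was not tested. Fewer arrays also leave fewer degrees of freedom.

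The number of genes that differed between days, 7749, lay between 5485 and 8598 in fits of all genes. Quantile normalization, run on the centred values, changed the counts to 603 for day 2 against day 0, 1898 for day 7 against day 5, 14 for day 11 against day 9 and 4146 for day 11 against day 0. It turned the medians of the Nodal and Activin targets (0.027) and Wnt targets (-0.009) at day 2, brought the endothelial list past the threshold between days 7 and 11 (-0.13) and ended the calls of smooth muscle (0.20) and hepatic genes (0.22) there. Lists that still passed but whose median moved by over 1.5 times with it were, for day 2 against day 0, BMP (0.438), FGF and ERK (0.413), glycolysis (-0.23), epithelial (-0.395) and mesenchymal (0.543) genes, for day 11 against day 7 sarcomere genes (1.022) and for day 11 against day 9 hepatic genes (0.404). With only the 7632 genes at 8 or above, and so fewer tested, 4321 differed between days, with 668 for day 2 against day 0, 259 for day 7 against day 5, 13, 887 and 3346 for day 11 against days 9, 7 and 0. There 12 lists held fewer than 5 genes and got no value, the definitive endoderm (0.215 for day 2 against day 0, -0.359 for day 9 against day 7), FGF and ERK (0.09), epithelial (-0.692 at day 2) and smooth muscle lists (0.127 for day 11 against day 7, -0.092 for day 9 against day 7) did not pass, and the epithelial list passed for day 5 against day 2 (0.428). For day 11 against day 9 the trend in the variance gave 12 genes. With the replicate number as a block it gave 5 (1 up, 4 down). Whether the numbers pair the arrays stays open: the labels do not say what they mark, and the replicate differences of 15 pairs of days correlated at -0.056 to 0.232, over 0 in 14 and over 0.1 in 8. With only the 4 arrays of the 2 days compared the counts were 860 (day 2 against day 0), 224 (day 5 against day 2), 154 (day 7 against day 5), 7 (day 9 against day 7) and 8 (day 11 against day 7). Without the day 2 arrays they were 968 for day 7 against day 5 and 1634 for day 9 against day 7.

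With an estimated correlation 48 of 62 list results were no longer past the threshold, 18 of them in the comparison planned for the list, at medians that this setting leaves as they were. For day 2 against day 0 these 18 were the streak (1.65), definitive endoderm (1.26), BMP (0.95), FGF and ERK (0.20), glycolysis (-0.38) and p53 (-0.74) lists; for day 5 against day 2 the mesenchymal (0.73), lateral mesoderm (1.80) and trophoblast (0.16) lists. For day 11 against day 7 they were the sarcomere (1.60), calcium handling (1.504), hormone and energy (0.63) and smooth muscle (0.60) lists, and for day 11 against day 0 the pluripotency (-3.63), matrix (1.05), hepatic (3.68), proliferation (-1.21) and HOX (0.25) lists. By fry, the Nodal and Activin list (median -0.035, but a mean of 0.50) and the housekeeping list (-0.40) passed. The smooth muscle (0.60), glycolysis (-0.38), sarcomere (day 7 against day 5, adjusted p = 0.114) and hepatic lists (day 11 against day 9, adjusted p = 0.313, and against day 7, adjusted p = 0.293) did not pass by fry, nor did 6 lists for day 9 against day 7 (adjusted p from 0.1 to 0.313). There the smooth muscle list (0.324) did not pass with the variance trend, the block or no day 2 arrays, nor the matrix list (0.233) with the last 2.

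Leaving out each array in turn gave counts from 680 to 1855 for day 2 against day 0, 191 to 3600 for day 5 against day 2, 104 to 824 for day 7 against day 5, 104 to 1916 for day 9 against day 7, 0 to 45 for day 11 against day 9, 503 to 2050 for day 11 against day 7 and 3948 to 5253 for day 11 against day 0. List medians ran at day 2 from 0.13 to 0.37 (FGF and ERK), -0.37 to -0.20 (glycolysis) and -0.17 to 0.29 (Nodal and Activin), and for day 7 against day 5 from 0.02 to 0.60 (cardiac transcription factors). Between days 7 and 11 they ran from -0.48 to 0.01 (endothelial), -0.157 to 0.177 (surface antigens, with -0.076 and -0.002 between), 0.15 to 0.70 (smooth muscle), -0.055 to 1.615 (hepatic) and -0.012 to 0.196 (epicardial). Against day 0, those of day 11 ran from -0.118 to 0.038 (neural ectoderm), -0.106 to 0.015 (neural crest), -0.006 to 0.24 (haematopoietic) and 0.22 to 0.27 (HOX), and the hepatic list against day 9 from -0.086 to 1.577. Other medians that moved by over 1.5 times, in lists that kept passing, ran from 0.667 to 2.067 (definitive endoderm), 0.169 to 0.481 (Wnt) and -0.992 to -0.296 (pluripotency) for day 2 against day 0, and for day 5 against day 2 from 0.404 to 0.985 (mesenchymal), 0.15 to 0.275 (trophoblast), -1.701 to -0.768 (streak), -1.709 to -1.027 (Nodal and Activin) and -0.539 to -0.227 (proliferation). They ran from 0.335 to 1.79 (sarcomere, day 7 against day 5), 0.383 to 1.937 (sarcomere, day 9 against day 7), -0.091 to 0.387 (smooth muscle there, not always passing) and, for day 11 against day 7, 0.616 to 2.373 (sarcomere), 0.735 to 1.441 (calcium handling) and 0.466 to 1.065 (hormone and energy). NKX2-5 between days 5 and 7 ran from -0.173 to 1.496.

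Among the named genes, counted once per comparison, quantile normalization ended 34 calls (adjusted p from 0.052 to 0.502): CHAC1, CLDN6, DUSP5, MSX2, PFKFB4, PFKP, PRDM1, SLC2A1 and TBXT for day 2 against day 0, CLDN6 for day 5 against day 2, GJA1, LDB3 and RAB25 for day 9 against day 7, DHCR7, DYNLT5, FGG, NSDHL, OIT3, PCDHB14, POSTN and SERPIND1 for day 11 against day 9, AFP, EPCAM, GJA1, LDB3, PDGFRA, PLN, SERPINA1, SIRPA and SMPX for day 11 against day 7, and DCX, ERBB3, ITGA2B and TBP for day 11 against day 0. The block left 18 without a call (adjusted p from 0.0506 to 0.0701): CHAC1 and CLDN6 at day 2, GATA4 for day 7 against day 5, ESRP2 and RAB25 for day 9 against day 7, PDGFRA and SIRPA for day 11 against day 7, and for day 11 against day 9 DHCR7, DYNLT5, FGG, HMGCS1, MLIP, NPY, NSDHL, OIT3, PCDHB14, POSTN and SERPIND1. The variance trend ended 16 (adjusted p from 0.0524 to 0.192): CLDN6 against day 0 and again for day 5 against day 2, GATA4 and VCAM1 for day 7 against day 5, LDB3 for day 9 against day 7, PDGFRA, SIRPA and SMPX for day 11 against day 7, and for day 11 against day 9 DHCR7, DYNLT5, FGG, MLIP, OIT3, PCDHB14, SERPIND1 and THBS4. Centring each array ended CLDN6 at day 2 and RAB25 for day 9 against day 7, and the fit without day 2 arrays FGG for day 11 against day 9. The fits of 4 arrays ended 86, and leaving out single arrays ended 200 (counted once per array left out) and brought 7 past the threshold. KIT between days 7 and 11 passed with the block, with the variance trend and without the day 2 arrays, and CDH1 at day 2 and NKX2-5 between days 7 and 11 with only the genes at 8 or above. Centring each array and taking the highest probe set left each count of changed genes within 1.5 times its value and each list on its side of the threshold.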

Other observations

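The 10 gene families tested for this part were chosen after the data were seen, in 70 tests over 7 comparisons; 36 passed with camera at the preset correlation and 0 with an estimated correlation (lowest adjusted p = 0.543). Of 11 metallothioneins, which bind zinc and copper, 10 fell between day 0 and day 11 (median -2.06; -1.80 after quantile normalization and -2.04 with each array centred; camera adjusted p = 0.00029, 0.691 with an estimated correlation). Their median relative to day 0 stood at -0.46 and -2.01 on replicates 1 and 2 of day 2, and at -2.39 and -2.42 at day 5. Of 16 protocadherin beta genes 7 rose between day 7 and day 11 (median 0.56; 0.71 after quantile normalization and 0.56 with each array centred; camera adjusted p = 2.6e-08, 0.543 with an estimated correlation), and the median per array stood at -0.28 and -0.30 at day 7 and at 0.39 and 0.11 at day 11. The microRNA precursors MIR302A and MIR302B, the only members of the MIR302 and MIR367 cluster among the genes tested, fell between day 0 and day 11 (median -5.04; -4.35 after quantile normalization and -5.02 with each array centred; camera adjusted p = 0.0719), and stood at -3.81 and -0.03 on replicates 1 and 2 of day 7.

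Between day 0 and day 11, 82 of 339 olfactory receptor genes rose and 0 fell (median 0.22; 0.24 after quantile normalization and 0.24 with each array centred; camera adjusted p = 1.14e-10, 0.543 with an estimated correlation); whether this reflects background was not tested. Of 61 ribosomal protein genes 30 fell and 1 rose (median -0.35; -0.25 and -0.33 in these 2 scalings; camera adjusted p = 2.26e-05, 0.643 with an estimated correlation). Of 54 replication-dependent histone genes 19 fell and 0 rose (median -0.38, with -0.29 and -0.37 in these scalings, camera adjusted p = 0.00886, 0.799 with an estimated correlation). Between day 0 and day 2, however, 12 of them rose and 0 fell (median 0.51, camera adjusted p = 3.17e-16, 0.543 with an estimated correlation). For day 11 against day 0, of 438 zinc finger genes named ZNF 125 fell and 40 rose (median -0.13, with -0.08 and -0.12 in these scalings, camera adjusted p = 0.0377, 0.799 with an estimated correlation). Of 176 small nucleolar RNAs 38 fell and 8 rose (median -0.09, with -0.04 and -0.07 in these scalings, camera adjusted p = 0.233). Of 11 genes of retinoic acid metabolism 3 rose and 2 fell (camera adjusted p = 0.454), and of 10 immediate-early genes 1 fell (camera adjusted p = 0.669). In every comparison the median of the olfactory receptor genes was opposite in sign to that of genes at 8 or above. For day 11 against day 0 these medians were 0.22 and -0.14. The balance of rises and falls thus depended on the level of the genes tested. No explanation of these values was tested.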
